A study of Homo sapiens with 17 samples.

How the data were processed

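Skin biopsies of patients with discoid lupus erythematosus, a scarring form of lupus confined mainly to the skin, were profiled as whole tissue on Affymetrix gene expression arrays. Per the labels, 17 arrays came from 7 patients. Each patient gave 1 lesional sample, and 4 patients gave 1 and 3 patients gave 2 non-lesional samples, which makes 7 lesional and 10 non-lesional arrays. Per the labels' protocols, biopsies were kept in an RNA preservative, RNA was purified over columns, and biotin-labelled cRNA was hybridised. The deposited table holds log2 expression values, which per the submitters' processing notes were made by the authors with RMA (background correction, quantile normalization and summary of probes) in the affy package; the versions are not given in the sources used here. Array medians ran from 6.69 to 6.78. The values are levels, not ratios to a sample. Scanner intensities, detection calls, scan dates and chip batches were not analysed here, so neither a dim limit nor a batch could be tested.

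The table held 12264 probe sets, 1 for each Entrez gene ID. The platform annotation gave 1 gene symbol for 11727 of them, several for 0, and did not list 537, which stayed unnamed but were kept in every test. Symbols were updated through the Entrez ID with the RefSeq gene table of GRCh38.p14, used only for names. No genome build is given for the array, so no coordinates are printed. No control probe set was among them.

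The following choices were made before the data were examined: the groups, the tests, the rule for named genes, 45 gene lists and the alternatives. The 2 non-lesional log2 values of a patient were averaged, so that 7 lesional and 7 non-lesional values entered the test and the patient was the replicate. Lesional minus non-lesional differences were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no filter and no covariate. P-values were two-sided and Benjamini-Hochberg adjusted over all 12264 probe sets, and a gene was called at an adjusted p under 0.05. Errors of a gene's log2 difference are the standard errors of that fit. Gene lists with at least 5 measured members were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 45 lists, and again with an estimated correlation and with fry. Errors of a list are the SD over 7 patients of the mean log2 difference of its members. Exact sign-flip tests over 7 patients cannot give a two-sided p below 0.0156. Correlations over patients were tested by exact permutation.

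The lists covered type I interferon and interferon-gamma responses, class I and class II antigen presentation, nucleic acid sensing, programmed cell death, immune checkpoints, complement, lymphoid chemokines, NF-kB cytokines, interleukin 17 and type 2 responses, T cells, cytotoxic lymphocytes, B cells, plasma cells, plasmacytoid and conventional dendritic cells, macrophages, Langerhans cells, mast cells and neutrophils. They also covered basal, differentiating and stressed keratinocytes, hair follicle, sebaceous and sweat glands, melanocytes, Merkel cells and nerve, fibroblast matrix, TGF-beta response, matrix degradation, blood and lymphatic endothelium, smooth muscle, skeletal muscle, fat, blood, cell cycle, oxidative phosphorylation, circadian clock, nuclear receptor metabolism, immediate early genes and housekeeping genes. Some genes stand in more than 1 list.

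The named genes were, among those called with the same sign in all 7 patients, the 15 with the largest positive and the 10 with the largest negative difference, and in each list up to 4 called members with the largest absolute difference, or 2 where none was called. XIST, Y-linked genes and genes with common whole-gene deletions in people were left out. Other genes in the text were chosen after their values were seen. So were the gene families in the closing part: 30 families defined by gene symbol were looked at with their values, of which 10 were picked for description and 20 genes named from them, and others are given where they were called. Of the 30, 28 had at least 3 genes outside the fixed lists, and their p-values were adjusted over these 28. A count over sex-linked genes found 0 patients whose arrays disagreed.

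Lesional and non-lesional samples with the same number came from the same patient, per the labels. Their deviations from the group means correlated at 0.18 to 0.55, each patient's own number giving the highest value for 7 of 7, so the numbers pair the samples. The fit with the patient as a block was an alternative fixed beforehand. Further alternatives were the patient as a random block over 17 arrays, 17 arrays as separate samples, the first or the second non-lesional sample alone, quantile normalization again, arrays centred on their median, a variance trend with robust fitting, array weights, the dimmest 30 percent of genes left out, an adjusted p under 0.01, shared list members left out, and each patient left out in turn. The unpaired fit was tested on simulated data with the real gene means and spreads. Of 50 genes changed per size, they recovered 46% at a log2 difference of 0.5, 76% at 1, 94% at 2 and 96% at 3, with 14 false calls among 170. Of the simulated lists, 5 of 5 shifted and 0 of 40 unchanged lists were called. The simulated genes varied independently of each other. The list result therefore does not cover lists whose members move together, such as the type I interferon list with an estimated correlation of 0.924. The number of arrays limits the precision.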

Results

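Gene expression was measured in whole skin biopsies of 7 patients with discoid lupus erythematosus, an inflammatory skin disease that leaves scars. The 7 lesional values were compared with the non-lesional values of the same 7 patients by an unpaired test, and a fit with the patient as a block was an alternative. The 7 lesional and 10 non-lesional arrays had median log2 levels between 6.69 and 6.78. The question, as far as the series states it, was what the transcriptome of lesional skin is.

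By camera with its preset correlation, the interferon-gamma and cytotoxic lymphocyte lists were higher in lesional skin, and the Langerhans cell, sweat gland and fat cell lists were lower. These calls were lost at adjusted p = 0.281 (interferon-gamma, cytotoxic and Langerhans), 0.341 (sweat gland) and 0.330 (fat cell) with an estimated correlation. CXCL11 (Entrez gene 6373), a chemokine that draws CXCR3-bearing T cells, was 39.4-fold higher (log2 difference 5.30 ± 1.19, adjusted p = 0.00927, limma, higher in 7 of 7 patients). The related chemokine CXCL9 (Entrez gene 4283) was 19.7-fold higher (4.30 ± 0.85, adjusted p = 0.00607, 7 of 7). GZMB (Entrez gene 3002), a protease of cytotoxic granules, was 18.6-fold higher (4.22 ± 0.89, adjusted p = 0.00735, 6 of 7). CD207 (Entrez gene 50489), the langerin of Langerhans cells, was 5.30-fold lower (−2.41 ± 0.42, adjusted p = 0.00465, lower in 6 of 7).

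Of 12264 genes, 2748 (22.4%) changed, 1283 of them higher and 1465 lower in lesional skin. At least 2-fold, 527 rose and 210 fell. In all 7 patients, 632 of the increases and 781 of the decreases had the same sign. After CXCL11 and CXCL9, the largest increases with a positive sign in every patient were those of CCL8 (17-fold), PLAC8 (16.1-fold), the DNA sensor AIM2 (15.9-fold), TFEC (15.9-fold) and the antiviral RSAD2 (12.9-fold). ADAMDEC1, CCL5, LILRB2, the tryptophan-degrading enzyme TDO2, ISG15, IFIT2, CD38 and the integrin ITGA4 followed with 10.7-fold to 7.47-fold increases. In patient 7 some of these were close to 0, such as 0.04 for PLAC8, 0.03 for ITGA4, 0.06 for IFIT2 and 0.07 for CD38 on the log2 scale. The largest decreases with a negative sign in every patient were those of the fatty acid binding protein FABP7 and the transferrin gene TF, 5.11-fold each, and CD1E (4.62-fold), RNF128 (4.47-fold), RERGL (4.17-fold) and CLDN8 (4.05-fold). GPD1 fell 3.99-fold, the interleukin 20 receptor chain IL20RA 3.97-fold, HSD11B1 3.94-fold and FMO1 3.70-fold.

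**Figure D1:**
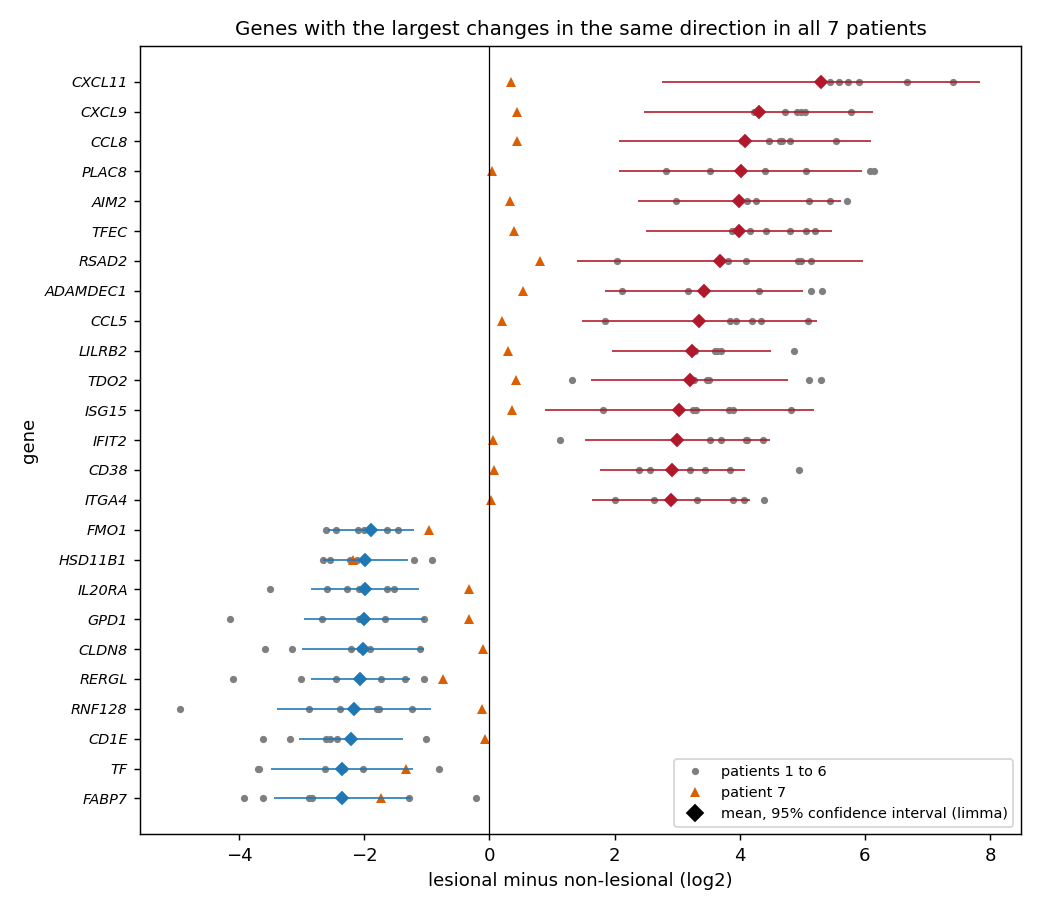
Differences of 25 genes between lesional and non-lesional skin (x axis, log2) for the genes with the largest changes of 1 sign in 7 patients (y axis). Diamonds and bars are means with 95% confidence intervals, circles are patients 1 to 6 and triangles are patient 7. CXCL11 had the largest increase, 5.30, and patient 7 lay at 0.35 for it while the others lay between 5.44 and 7.41.

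The lesional sample of patient 7 did not share most of the change of the other 6. On a scale from the mean non-lesional (0) to the mean lesional sample (1) of the other patients, it lay at −0.0141, inside the range of the 10 non-lesional arrays (−0.140 to 0.0788), while the other 6 lesional arrays lay between 0.762 and 1.55. The scale was set anew for each patient. For patients 1 to 6 its lesional mean included the lesional array of patient 7, so positions of different patients are not on the same scale. Some decreases were shared. In patient 7 the oxidative phosphorylation list differed by −0.38 (−0.457 to −0.106 in the others) and the melanocyte list by −0.484 (−1.44 to −0.170). The sebaceous list differed by −1.53 (−1.72 to 0.420). Lists in which patient 7 lay far from the others are given further below. Leaving out patient 7 gave 4034 changed genes. Leaving out patient 1, 2, 3, 4, 5 or 6 gave 1226, 1308, 1755, 2073, 1678 or 1076. Of 146 genes named by the fixed rule and called in limma, 71 were called without each of the patients in turn, and the call of 75 ended without at least 1 of them, 67, 64, 41, 37, 44 or 71 without patient 1, 2, 3, 4, 5 or 6 and 1 without patient 7. The highest adjusted p of CXCL11, CXCL9, GZMB and CD207 over these fits was 0.0412, 0.0337, 0.037 and 0.0294, each without patient 6. Leaving out patient 7 moved the fold of 19 of these 146 genes by over 1.5 times, to 69.8-fold for CXCL11, 30.8-fold for CXCL9, 25.9-fold for CCL8, 25.5-fold for PLAC8, 24.3-fold for AIM2, 24-fold for TFEC, 16.7-fold for ISG20, 39.5-fold for CXCL10 and 22.9-fold for IDO1. GZMB was then 31.6-fold, GZMK 10.5-fold, CXCL13 29.9-fold, SERPINB4 18.1-fold, SERPINB3 7.13-fold, KRT6C 11.3-fold and MMP1 43.1-fold higher, CCR7 was higher by 3.85 on the log2 scale, and SCGB1D2 19.8-fold and LEP 8.33-fold lower. Other patients moved 4 of these genes by as much: SCGB1D2 was 6.06-fold lower without patient 1 (adjusted p = 0.151) and 6.78-fold without patient 6 (0.137), LEP 3.6-fold without patient 1 (0.12), KRT6C 10.6-fold higher without patient 3 and CXCL13 22.4-fold without patient 4. With the patient as a block, 3258 genes changed, 2485 of them shared with the 2748. The first principal component held 47.1% of the variance.

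**Figure D2:**
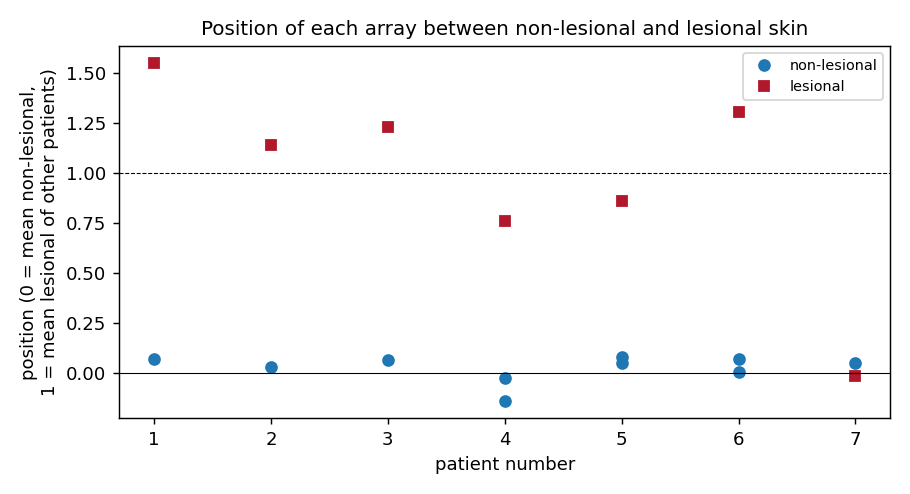
Position of each of 17 arrays (y axis, no unit) for each patient number (x axis), where 0 is the mean non-lesional and 1 the mean lesional value of the other patients. Squares are lesional and circles non-lesional arrays. The scale is set anew for each patient, and the lesional array of patient 7 enters the lesional mean for every other patient. The lesional array of patient 7 lay at −0.0141, and the other lesional arrays lay between 0.762 and 1.55.

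Arrays of lesional and non-lesional skin of a patient were compared with pairs of non-lesional arrays. The median absolute log2 difference was 0.132 between 2 such non-lesional samples (3 pairs, 0.114 to 0.183), 0.2 between non-lesional samples of different patients (42 pairs) and 0.284 between lesional and non-lesional samples of a patient (10 pairs). These spreads are descriptions of 17 arrays without a test. The labels do not say whether the 2 non-lesional samples of a patient are separate biopsies or repeat arrays of 1 biopsy, so the first value may hold technical spread only.

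Most measured interferon response genes rose. Of 32 measured type I interferon response genes, 26 rose (31 adjusted over the list alone, 32 with the patient as a block, 32 with patient 7 left out), and the list was 2.30 ± 1.13 (SD, n = 7) higher on the log2 scale. Examples were RSAD2, the exonuclease ISG20 (10.4-fold) and OASL (10.2-fold). Of 20 interferon-gamma response genes, 19 rose (19 adjusted over the list alone), by 2.38 ± 1.09 on average, among them CXCL10 (23.2-fold) and the tryptophan-degrading IDO1 (14-fold). Nucleic acid sensors rose in 13 of 16 (16 adjusted over the list alone), including TLR7 (6.73-fold), the transcription factor IRF7 (5.76-fold) and the RNA helicase IFIH1 (4.44-fold), by 1.52 ± 0.70. All 3 lists were called by camera, with adjusted p = 1.69e-14, 5.07e-13 and 1.01e-09. These calls were lost at adjusted p = 0.281 with an estimated correlation. With patient 7 left out as well, the interferon-gamma list was called at adjusted p = 0.0311 with an estimated correlation.

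**Figure D3:**
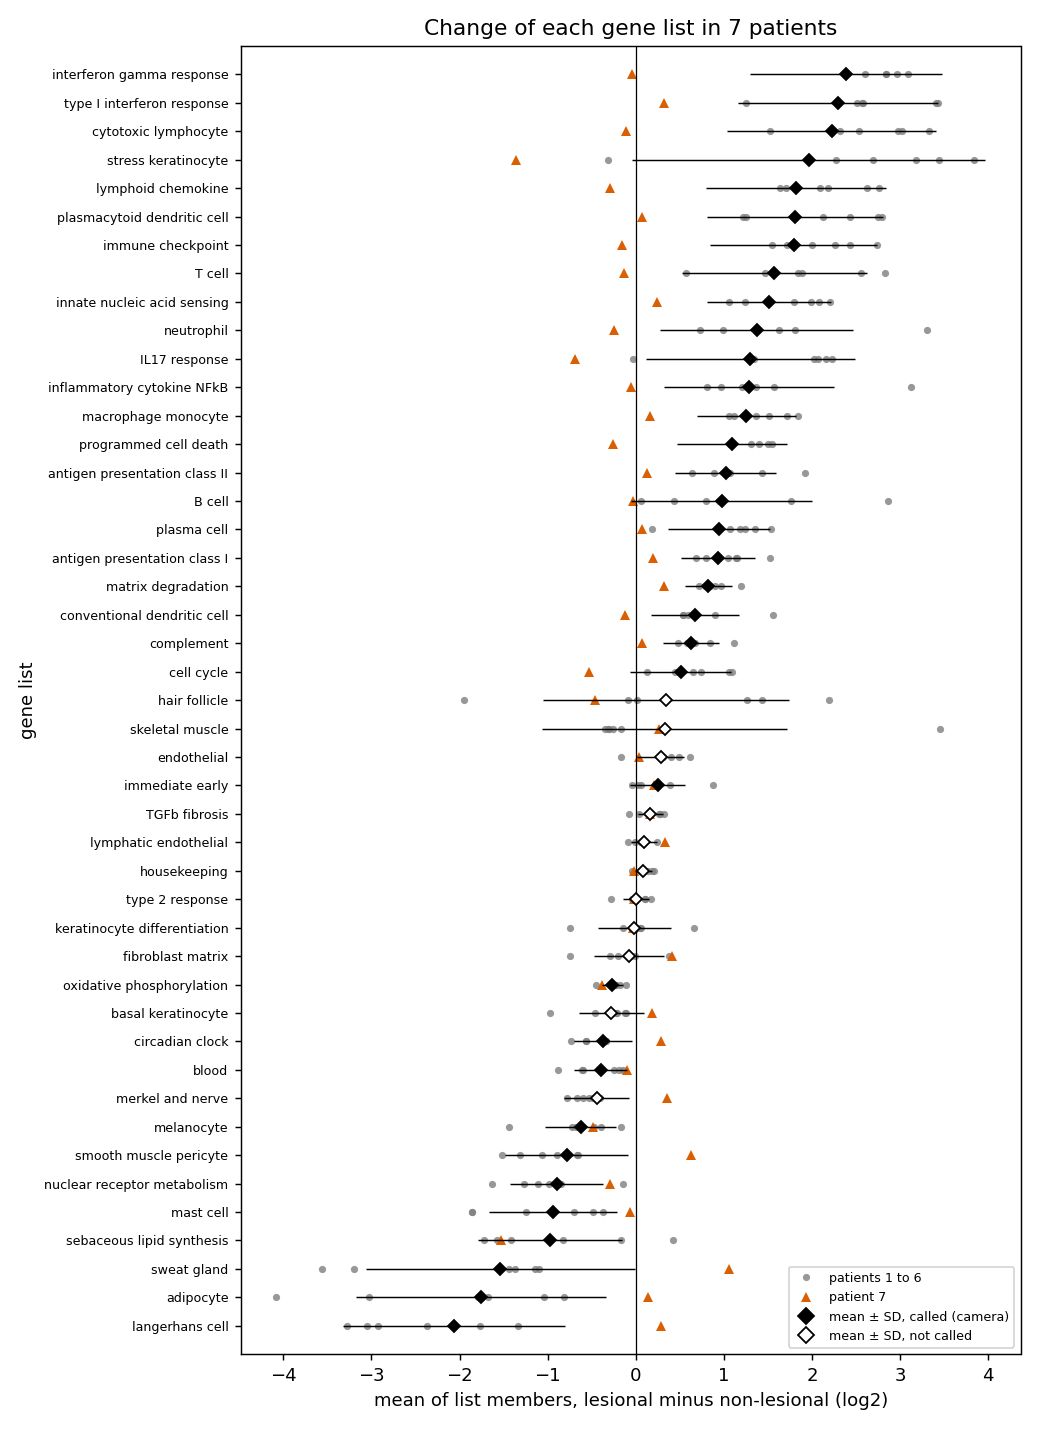
Mean lesional minus non-lesional difference of the members of each of 45 gene lists (x axis, log2; y axis, list). Diamonds with bars are means ± SD over 7 patients, filled where camera with its preset correlation called the list, circles are patients 1 to 6 and triangles patient 7. The interferon-gamma list had the highest mean, 2.38, and the Langerhans cell list the lowest, −2.06.

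Antigen presentation lists were higher in lesional skin by camera with its preset correlation. In class I presentation, 7 of 14 genes rose (11 adjusted over the list alone, 13 with the patient as a block, 13 with patient 7 left out), including the immunoproteasome subunits PSMB9 (3.67-fold), PSMB10 (3.35-fold) and PSMB8 (2.35-fold) and the peptide transporter TAP1 (3.29-fold). In class II presentation, 7 of 10 rose (7 adjusted over the list alone), including CTSS (3.98-fold), HLA-DMB (2.57-fold), CD74 (2.41-fold) and HLA-DOB (2.30-fold). The lists were 0.93 ± 0.42 and 1.02 ± 0.57 higher (camera adjusted p = 2.72e-06 and 4.18e-05). Both calls were lost, at adjusted p = 0.313 with an estimated correlation for class I and adjusted p = 0.300 with an estimated correlation for class II.

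Cytotoxic lymphocyte and T cell lists were higher in lesional skin by camera with its preset correlation. Of 21 cytotoxic lymphocyte genes, 20 rose (21 adjusted over the list alone), by 2.23 ± 1.19, among them GZMB, CCL5 (10.2-fold), GNLY (8.94-fold) and GZMK (6.82-fold). Of 21 T cell genes, 18 rose (19 adjusted over the list alone, 18 higher and 1 lower with patient 7 left out), by 1.57 ± 1.05, among them the costimulator ICOS (6.23-fold), CD2 (5.92-fold), CD247 (5.12-fold) and the receptor constant gene TRBC1 (4.66-fold). Immune checkpoint genes rose in 7 of 8 (7 adjusted over the list alone), by 1.79 ± 0.95, with LAG3 at 6.15-fold, IL10RA at 4.10-fold and CD96 at 3.41-fold. The cell death list rose in 12 of 12 genes (12 adjusted over the list alone), by 1.09 ± 0.62, including the death ligand FASLG (2.84-fold), its receptor FAS (2.81-fold), TNFSF10 (2.66-fold) and CASP1 (2.41-fold). Camera called these 4 lists (adjusted p from 8.62e-13 to 2.03e-05), and each call was lost at adjusted p = 0.281 with an estimated correlation.

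Antibody-producing cells gave a less uniform picture. Of 15 B cell genes, 2 rose (1 adjusted over the list alone), namely CD72 (3.12-fold) and PAX5 (1.19-fold, adjusted p = 0.0492, and 0.0747 with the patient as a block). The B cell list was 0.97 ± 1.03 higher and called (adjusted p = 0.000315), but not with fry (adjusted p = 0.0733) nor at adjusted p = 0.353 with an estimated correlation. Of 12 plasma cell genes, 3 rose and 1 fell (5 and 1 adjusted over the list alone, 6 and 1 with the patient as a block, 5 and 1 with patient 7 left out). CD38 (7.57-fold), the survival receptor TNFRSF17 (3.96-fold) and FKBP11 (2.29-fold) rose, and SDC1, which keratinocytes also express, fell 1.72-fold. The immunoglobulin genes IGHM (log2 2.06, adjusted p = 0.101), JCHAIN (1.16, adjusted p = 0.282) and IGKC (0.92, adjusted p = 0.514), chosen after their values were seen, did not pass, though with the patient as a block IGHM (adjusted p = 0.0306) and JCHAIN (adjusted p = 0.0361) did. The plasma cell list was 0.95 ± 0.58 higher (adjusted p = 0.00308; adjusted p = 0.313 with an estimated correlation).

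Myeloid and dendritic cell lists were higher in lesional skin. Macrophage genes rose in 13 of 20 (17 adjusted over the list alone, 17 with the patient as a block), by 1.25 ± 0.56, with FPR3 and CLEC7A at 4.59-fold, the complement component C1QB at 3.86-fold and CD68 at 3.59-fold. Plasmacytoid dendritic cell genes rose in 8 of 11 (8 adjusted over the list alone), by 1.81 ± 0.999, including PLAC8, IRF8 (6.16-fold) and the surface receptor LILRA4 (5.18-fold). Neutrophil genes rose in 5 of 13 (7 adjusted over the list alone), by 1.37 ± 1.10, including MMP9 (7.02-fold), FPR1 (4.55-fold), MNDA (4.48-fold) and S100A12 (4.38-fold, adjusted p = 0.0289, and 0.0542 with the patient as a block). These 3 lists were called (adjusted p from 1.95e-09 to 0.000156), each call being lost at adjusted p = 0.281 with an estimated correlation. Among 14 conventional dendritic cell genes, 6 rose and 3 fell (7 and 3 adjusted over the list alone). The maturation markers CCR7 (9.29-fold), CD86 (4.48-fold) and CD83 (3.8-fold) rose, while the IgE receptor chain FCER1A fell 4.13-fold. That list was 0.67 ± 0.50 higher (adjusted p = 0.0458; adjusted p = 0.353 with an estimated correlation). Its call ended without patient 1 (adjusted p = 0.0567), 2 (0.0508), 3 (0.117) or 5 (0.0632), with the second non-lesional sample alone (0.0632), without the dimmest genes (0.0727), without shared members (0.0911) and with fry (0.0790).

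Langerhans cell and mast cell markers fell. Of 6 Langerhans cell genes, 5 fell (6 adjusted over the list alone), and the list was lower by −2.06 ± 1.26, with FCGBP at 5.46-fold, CD207 at 5.30-fold, CD1A at 5.09-fold and CD1E at 4.62-fold. Of 8 mast cell genes, 6 fell (7 adjusted over the list alone, 4 with the patient as a block), by −0.94 ± 0.72, including the prostaglandin D synthase HPGDS (2.86-fold), CPA3 (2.56-fold), CTSG (2.26-fold) and KIT (1.98-fold, adjusted p = 0.0248, and 0.0625 with the patient as a block). Both lists were called (adjusted p = 5.64e-05 and 0.000173), and both calls were lost at adjusted p = 0.281 with an estimated correlation.

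Lists of lymphoid chemokines, NF-kB cytokines and the interleukin 17 response were read together. Lymphoid chemokines and receptors rose in 10 of 16 (13 adjusted over the list alone), by 1.82 ± 1.02, including CXCL13, which draws B cells and is made by follicular helper T cells (14.7-fold), CCR7 and IL7R (6.10-fold). NF-kB cytokine genes rose in 10 of 18 (14 adjusted over the list alone), by 1.28 ± 0.97, including CXCL1 (4.89-fold), CXCL2 (4.62-fold), TNFAIP6 (4.41-fold) and PTGS2 (3.63-fold). In the interleukin 17 response, 4 of 12 rose (6 adjusted over the list alone, 2 with the patient as a block), by 1.30 ± 1.19. SERPINB4 (9.16-fold, adjusted p = 0.0429, and 0.0568 with the block), SERPINB3 (4.52-fold, adjusted p = 0.0292, and 0.0599 with the block) and IL36G (3.53-fold) belonged to these, while IL17A and IL22, chosen after their values were seen, stood at log2 differences of 0.02 and 0.02. SERPINB3 and SERPINB4 are near-identical genes, and cross-hybridisation between them was not tested. The 3 lists were called (adjusted p = 9.52e-07, 1.18e-07 and 0.00103), each call being lost at adjusted p = 0.281 with an estimated correlation, and the interleukin 17 call also ended without shared members, where the mean was 0.15 (adjusted p = 0.286; 7 of the 12 genes stand in another list). Without the dimmest genes that mean was 2.12. Type 2 response genes were not called as a list (0.00 ± 0.15, adjusted p = 0.458), with 2 of 14 higher and 1 lower (2 and 1 adjusted over the list alone), namely IL4R (1.95-fold) and IL10 (1.72-fold) higher and GATA3 2.08-fold lower.

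Complement genes rose in 9 and fell in 3 of 16 (10 and 4 adjusted over the list alone). The alternative pathway protease CFB rose 6.27-fold and the receptor C3AR1 3.43-fold, while the terminal component C7 fell 3.49-fold. The list was 0.63 ± 0.32 higher (adjusted p = 0.00698; adjusted p = 0.300 with an estimated correlation).

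Keratinocyte genes were read in 3 lists. Of 13 stress keratinocyte genes, 6 rose (11 adjusted over the list alone, 11 with patient 7 left out, 2 with the patient as a block), by 1.96 ± 2.0, the list being lower in patients 3 and 7. KRT6C, a keratin of a near-identical family, was 6.92-fold higher (adjusted p = 0.0219, and 0.0518 with the block). The list was called (adjusted p = 8.27e-06), and the call was lost at adjusted p = 0.281 with an estimated correlation. Of 10 basal keratinocyte genes, 1 fell (1 adjusted over the list alone, 2 with the block, 3 with patient 7 left out), KRT15, a keratin of the basal layer and the follicular bulge, by 3.46-fold. The basal list stood at −0.28 ± 0.36 (adjusted p = 0.313). Of 18 differentiation genes, 1 fell (0 adjusted over the list alone, 2 higher and 1 lower with patient 7 left out), the desmosomal DSG1, by 1.64-fold, and the list stood at −0.02 ± 0.41 (adjusted p = 0.590).

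Sweat gland, sebaceous and melanocyte lists were lower in lesional skin. Sweat gland genes fell in 6 of 12 (9 adjusted over the list alone, 3 with the patient as a block, 11 with patient 7 left out), by −1.54 ± 1.53. SCGB1D2 was 11.4-fold lower (adjusted p = 0.0464, and 0.0586 with the block), SCGB2A1 4.28-fold, the water channel AQP5 3.01-fold and SLC12A2 2.54-fold. Melanocyte genes fell in 3 of 14 (8 adjusted over the list alone, 6 with the block, 5 with patient 7 left out), by −0.62 ± 0.40, including MLANA (2.63-fold) and OCA2 (2.35-fold). Both lists were called (adjusted p = 0.00144 each), with adjusted p = 0.341 with an estimated correlation for sweat glands and adjusted p = 0.313 with an estimated correlation for melanocytes. The sebaceous and lipid synthesis list was −0.97 ± 0.82 lower (adjusted p = 0.00624; adjusted p = 0.440 with an estimated correlation), with 1 of 17 genes lower (0 adjusted over the list alone, 9 with the block, 2 with patient 7 left out), ACACA at 1.61-fold. Its call ended without patient 7 (adjusted p = 0.0528) and with fry (adjusted p = 0.0733). None of the 16 hair follicle genes passed in limma (0 higher and 0 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, 2 lower with the block, 1 lower with patient 7 left out), and patients ranged from −1.95 to 2.19 around a mean of 0.34 ± 1.39 (adjusted p = 0.398). KRT34 and KRT35 stood at 1.42 ± 1.66 (adjusted p = 0.564) and 1.17 ± 1.66 (adjusted p = 0.643). Merkel cell and nerve genes stood at −0.44 ± 0.37 (adjusted p = 0.0609), a list called with the patient as a block (adjusted p = 0.0391), as a random block (0.0492), with the second non-lesional sample alone (0.0447), with array weights (0.0302), with fry (0.0153), without patient 7 (0.0211) and without patient 7 under the block (0.00754). It was not called at adjusted p = 0.341 with an estimated correlation, nor at adjusted p = 0.174 with an estimated correlation and patient 7 left out. Of its 9 genes, ERBB3 fell, by 2.22-fold (1 adjusted over the list alone, 2 with the block, 5 with patient 7 left out).

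**Figure D4:**
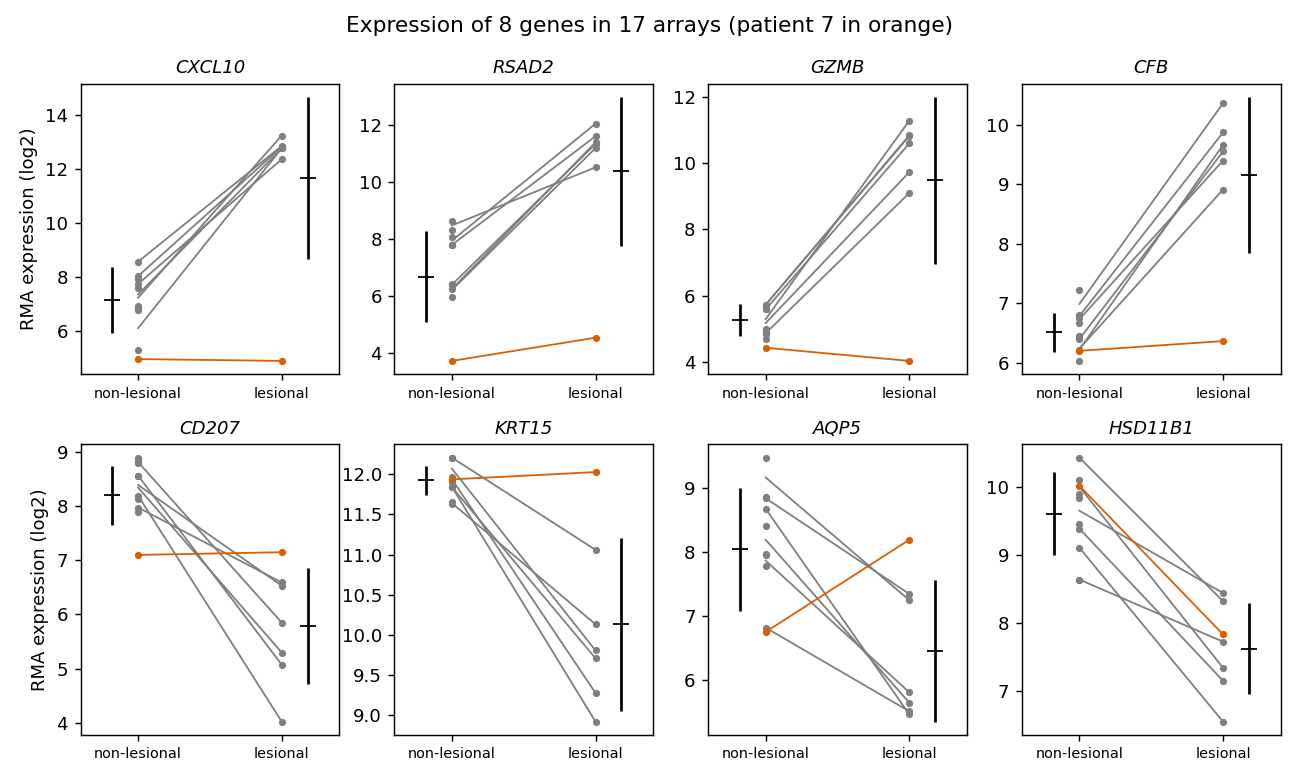
RMA expression (y axis, log2) of 8 genes in 10 non-lesional and 7 lesional arrays (x axis). Circles are arrays, lines join the lesional array of a patient to the mean of that patient's non-lesional arrays, bars are the mean ± SD over 7 patients, and patient 7 is in orange. CXCL10 was 23.2-fold higher on average, and KRT15 was 3.46-fold lower.

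The matrix degradation list was higher and the smooth muscle and fat cell lists were lower in lesional skin. Matrix degradation genes rose in 6 and fell in 1 of 19 (7 and 1 adjusted over the list alone), the collagenase MMP1 by 23.7-fold, MMP9 by 7.02-fold, the inhibitor TIMP1 by 2.71-fold and PLAUR by 2.31-fold, and the list was 0.82 ± 0.27 higher (adjusted p = 0.000255; adjusted p = 0.281 with an estimated correlation). Fat cell genes fell in 4 of 12 (11 adjusted over the list alone, 6 with the patient as a block, 7 with patient 7 left out), by −1.76 ± 1.42, including the hormone LEP (5.51-fold), GPD1 (3.99-fold), CIDEC (3.94-fold) and PPARG (2.12-fold, adjusted p = 0.0458, 0.0703 with the patient as a block and 0.0502 without patient 7). Smooth muscle and pericyte genes fell in 4 of 12 (8 adjusted over the list alone, 8 with patient 7 left out), by −0.78 ± 0.70, including RGS5 (2.15-fold), TAGLN (1.99-fold), ACTA2 (1.80-fold, adjusted p = 0.0469, and 0.0605 with the block) and NOTCH3 (1.62-fold). These 2 lists were called (adjusted p = 0.000551 and 0.00144), at adjusted p = 0.330 with an estimated correlation for fat cells and adjusted p = 0.353 with an estimated correlation for smooth muscle.

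Fibroblast matrix genes moved in both directions. Of 23 fibroblast matrix genes, 4 rose and 3 fell (4 and 5 adjusted over the list alone, 3 and 6 with patient 7 left out), THY1 being 2.15-fold higher and CFD 2.47-fold, FBLN1 1.95-fold and MFAP4 1.78-fold lower. The list stood at −0.07 ± 0.40 (adjusted p = 0.971), with camera's direction opposite to the mean. Of 21 TGF-beta response genes, 1 rose and 2 fell (5 and 2 adjusted over the list alone, 5 and 1 with the block, 3 and 3 with patient 7 left out), TGFB3 being 1.61-fold higher (adjusted p = 0.0287, and 0.0561 with the block). That list stood at 0.17 ± 0.14 (adjusted p = 0.0651) and was called with the block (adjusted p = 0.0231), without patient 1 (0.0492), 3 (0.0276) or 6 (0.0321), and without shared members (0.0117), but not at adjusted p = 0.357 with an estimated correlation, nor at adjusted p = 0.523 with an estimated correlation and patient 7 left out. Endothelial genes rose in 4 and fell in 2 of 17 (4 and 2 adjusted over the list alone), with the leukocyte adhesion molecules SELE (4.95-fold), VCAM1 (4.50-fold) and SELP (2.0-fold) higher and EMCN 1.75-fold lower. The endothelial list was not called (0.28 ± 0.27, adjusted p = 0.210), except without patient 1 (adjusted p = 0.0343), and stood at adjusted p = 0.647 with an estimated correlation. Of 9 lymphatic endothelial genes, PDPN rose, by 1.85-fold (0 adjusted over the list alone, 2 with the block, 2 higher and 2 lower with patient 7 left out), and the list stood at 0.09 ± 0.14 (adjusted p = 0.590). None of 14 skeletal muscle genes passed in limma (0 higher and 0 lower at an unadjusted p under 0.05, 0 adjusted over the list alone), TTN standing at 0.97 ± 0.54 (adjusted p = 0.204) and MYH2 at 0.83 ± 0.80 (adjusted p = 0.472), and the list at 0.33 ± 1.39 (adjusted p = 0.293). None of 9 blood genes passed in limma (4 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, 2 lower with the block, 1 lower with patient 7 left out), HBB standing at −1.13 ± 0.39 (adjusted p = 0.0537, and 0.0297 with the block) and PPBP at −0.56 ± 0.24 (adjusted p = 0.0996). The blood list was nevertheless called lower (−0.40 ± 0.30, adjusted p = 0.0422; adjusted p = 0.353 with an estimated correlation). That call ended without patient 3 (adjusted p = 0.0558), 4 (0.0643), 5 (0.0944) or 7 (0.0704), with array weights (0.131) and with quantile normalization again (0.0508).

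By camera with its preset correlation the cell cycle list was higher and the metabolic and clock lists lower. Of 25 cell cycle genes, 6 rose (6 adjusted over the list alone, 16 with patient 7 left out), including RRM2 (2.38-fold), MELK (2.15-fold), AURKA (1.75-fold) and CCNA2 (1.74-fold), and the list was 0.51 ± 0.57 higher (adjusted p = 3.56e-06; adjusted p = 0.353 with an estimated correlation). Oxidative phosphorylation genes fell in 9 of 21 (15 adjusted over the list alone, 14 with the block), each by a small amount such as 1.53-fold for UQCRC1, 1.4-fold for COX5B, 1.34-fold for NDUFB5 and 1.33-fold for ATP5PO, and the list was lower in 7 of 7 patients (−0.27 ± 0.12, adjusted p = 8.15e-05; adjusted p = 0.353 with an estimated correlation). Nuclear receptor and metabolism genes fell in 9 and rose in 1 of 24 (11 and 1 adjusted over the list alone), including the retinol carrier RBP4 (4.52-fold), HSD11B1, which makes cortisol from cortisone (3.94-fold), ALDH3A1 (2.56-fold) and FMO5 (2.31-fold). That list was −0.90 ± 0.53 lower (adjusted p = 0.00144; adjusted p = 0.281 with an estimated correlation). Clock genes fell in 5 of 16 (7 adjusted over the list alone), with HLF at 2.51-fold, RORA at 1.63-fold, CRY2 at 1.52-fold and TEF at 1.28-fold, and the list was −0.37 ± 0.33 lower (adjusted p = 0.0289; adjusted p = 0.392 with an estimated correlation). Its call ended without patient 4 (adjusted p = 0.0556) and without the dimmest genes (adjusted p = 0.0583).

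Genes that respond to handling and genes used as references were also read. Immediate early genes rose in 4 and fell in 1 of 18 (4 and 1 adjusted over the list alone, 5 and 3 with patient 7 left out), with ATF3 2.13-fold, KLF2 1.86-fold and ZFP36 1.74-fold higher and EGR3 1.60-fold lower. The list was 0.25 ± 0.31 higher, and 0.15 without patient 4 (adjusted p = 0.0421 over all 7; adjusted p = 0.474 with an estimated correlation). That call ended without patient 2 (adjusted p = 0.0663) or 7 (0.0848), with array weights (0.105), with 17 separate arrays (0.0665), with the first non-lesional sample alone (0.0537), without the dimmest genes (0.0911), without patient 7 under the block (0.0582) and with fry (0.236). Of 9 housekeeping genes, RPL13A fell, by 1.15-fold (1 adjusted over the list alone, 1 higher and 1 lower with patient 7 left out), and the list stood at 0.08 ± 0.10 (adjusted p = 0.293). Camera thus called 23 lists higher and 11 lower, and 0 with an estimated correlation, where 1 was higher and 1 lower at an unadjusted p under 0.05. With fry, which asks only whether a list's genes move one way, 20 were called higher and 11 lower.

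Relations between lists were read over the 7 patients. Of 7 relations between the type I interferon change and other list changes over 7 patients, the strongest was with cytotoxic lymphocytes (Pearson r = 0.836, exact permutation p = 0.0224, adjusted p = 0.157; Spearman rho = 0.929, exact permutation p = 0.00675, adjusted p = 0.0472). Without the 2 samples farthest from the median r was 0.654, and without patient 7 it was 0.533 (exact permutation p = 0.290), so the Pearson relation was not detectable without that patient. The Spearman relation did not pass without patient 7 either (rho = 0.886, exact permutation p = 0.0333, adjusted p = 0.233), a fit chosen after the data were seen, nor with the median over list members (rho = 0.893, exact permutation p = 0.0123, adjusted p = 0.0861). The other 6 had r between −0.680 and 0.582 with exact permutation p of at least 0.0847, and rho between −0.750 and 0.607 with exact permutation p of at least 0.0663.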

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

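The tests of chance were chosen before the result was seen, and the tests of patient 7, of the Langerhans, fat and sweat gland decrease and of the HOX genes only after it. Each patient's difference was compared with those of the other 6, and chance sets 1 value apart in about 5 percent of groups. Of 45 lists and 172 named genes, 20 of them family genes chosen after their values were seen, 8 lists and 37 genes had a patient far from the others, and 39 of these values belonged to patient 7.

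In patient 7 the interferon-gamma list differed by −0.0369 on the log2 scale (2.39 to 3.09 in the others), lymphoid chemokines by −0.297 (1.63 to 2.76), immune checkpoints by −0.156 (1.55 to 2.74) and cell death by −0.26 (1.07 to 1.54). Merkel cell and nerve genes differed by 0.354 (−0.783 to −0.406), smooth muscle by 0.623 (−1.52 to −0.658) and clock genes by 0.284 (−0.74 to −0.336). The chemokines CXCL11 (0.348), CXCL9 (0.437), CXCL10 (−0.0671) and CCL8 (0.445) stood far below the other patients. So did TFEC (0.392), LILRB2 (0.304), LILRB1 (0.683), ISG20 (−0.7), APOBEC3A (−0.408), IDO1 (−0.464), KYNU (−0.351), PSMB10 (−0.24) and CTSS (0.164). GZMB (−0.395), IL18RAP (0.378), CD48 (−0.368), IL10RA (−0.0398), CLEC7A (0.221), CD86 (0.146), CCR1 (0.149), CFB (0.163) and C3AR1 (0.26) did as well. FAS (−0.155), TNFSF10 (−0.15), CASP1 (−0.745) and TIMP1 (−0.268) completed these. Above the other patients stood GATA3 (0.622), AQP5 (1.44), SLC12A2 (1.12), ERBB3 (0.274), NOTCH3 (0.397) and FMO5 (0.754).

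The array of patient 7 labelled non-lesional lay at 0.0484 on the scale from non-lesional (0) to lesional (1). The SD among the other non-lesional positions was 0.0703. This argues against an exchange with a lesion that carried the change of the other patients. An exchange with a lesion without that change could not be seen, since both arrays of patient 7 lay near the non-lesional mean. Uninvolved skin and a lesion without the inflammatory change cannot be told apart, since both predict the position of −0.0141 and only 1 such array exists. Poor RNA or a failed array cannot be told apart from these: the Langerhans list, at a mean log2 level of 7.456, lay between the other lesional arrays (5.02 to 6.414) and the non-lesional arrays of the other patients (7.631 to 8.733), and that patient's own non-lesional array lay at 7.165; this test replaced earlier ones. No biological explanation was tested.

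Langerhans cell, fat cell and sweat gland lists were lower in the lesional samples of the patients other than patient 7. Dilution by infiltrating cells would lower all resident cells alike. The Langerhans list lay −1.79 ± 1.15 (SD, n = 7) from the mean of 9 other resident cell type lists. It was lower in 6 of 7 patients, and the 9 lists ranged from −0.973 to 0.343. The Langerhans list was taken up after the values were seen and had the lowest mean of all lists. Its place below the other lists was thus fixed by the choice, so this comparison cannot decide on dilution. The fat and sweat gland lists, also taken up after the values were seen, lay −1.37 ± 1.28 from the mean of the 9 lists. That is little more than 1 SD (lower in 6 of 7). Less deep tissue in the lesional biopsies may lie behind the fat and sweat gland part, whose changes correlated over 7 patients (Pearson r = 0.894, exact permutation p = 0.0119; Spearman rho = 0.607, exact permutation p = 0.167; r = 0.804 without the 2 farthest and 0.845 without patient 7). Any cause that lowers both lists gives such a correlation, so it does not single out depth. In patient 2, whose lesional array was high in skeletal muscle genes (3.45), the fat list still differed by −1.67. The sweat gland list of that patient differed by −1.14. Less deep tissue would leave Langerhans cells, which lie in the epidermis, level with keratinocytes. Their list lay −1.92 ± 1.31 from the basal and differentiation keratinocyte lists (lower in 6 of 7), a comparison with the same limit of choice. The tests against other lists replaced earlier ones with fewer or no reference lists. A difference in body site, raised below from the HOX genes, was not tested as a cause of these decreases.

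In patient 2 the skeletal muscle list differed by 3.45 (−0.349 to 0.265 in the others), TTN by 3.75 and MYH2 by 5.92, and 13 of 14 muscle genes were highest in that lesional array and at least 2-fold above its non-lesional array. In patient 4 CXCL1 differed by 5.43 (0.702 to 2.6) and ZFP36 by 1.85 (0.314 to 0.924). In patient 1 EMCN differed by −2.17 (−0.987 to −0.124).

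Chance alone is argued against for the count of 2748 changed genes: of 100 random splits of the 14 values, 1, the real one, gave as many, and the highest other gave 1. The splits test the count as a whole, so single genes among the 2748 may still be false calls. Of 64 splits that part every patient's pair, 2 gave as many, the real split and the one that exchanged only patient 7's pair, with 3087 genes. The other pair-parting splits, which exchanged other patients' pairs, gave fewer than 2748.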

How the results depend on the processing

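Patient 7 left out together with a block or an estimated correlation, the block with an estimated correlation and the gene families were chosen only after the result was seen; fry was fixed beforehand. Against 2748 changed genes (1283 higher, 1465 lower; 527 and 210 at least 2-fold), the patient as a random block over 17 arrays gave 4917 (2186 and 2731), array weights 4681 (2136 and 2545, 389 lower at least 2-fold), and the block without patient 7 gave 4713 (2058 and 2655, 454 lower at least 2-fold). An adjusted p under 0.01 gave 801 (388 and 413; 242 and 90 at least 2-fold). Leaving out 1 patient gave 1076 to 4034 changed genes, 498 to 1814 higher, 578 to 2220 lower, 285 to 687 higher and 88 to 416 lower at least 2-fold, the highest values without patient 7; fewer patients were tested in each. The replicate block gave 3258 (1469 and 1789), with 24 lists higher and 12 lower, and changed no other call of a list or of a gene named by the rule than those printed beside the results. Counts of list members with the block are printed for some lists only. No gene called in the 7 against 7 fit had the opposite sign in any refit of the genes (0). With an estimated correlation 0 lists were called higher and 0 lower by camera, also with the block (0 and 0), and 1 and 0 without patient 7; the cause was not tested. Over the alternatives, lists gave 888 results on the same side of the threshold, 129 weaker and 13 stronger, the 172 named genes, 20 of them from the families, 2691, 371 and 18, and families 481, 16 and 7. The mean of probe sets, the probe set of largest variance and the probe set level were not run, since each gene had 1 probe set. The number of arrays limits the precision, and signal over background was not analysed here.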

Other observations

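All gene families and tests in this part were chosen after the values were seen. Of 30 families looked at, 28 were tested, and camera called 8 higher and 4 lower; with an estimated correlation it called 0. Ribosomal protein genes outside the fixed lists fell in 23 of 26, from 1.17-fold for RPL37A to 1.87-fold for RPL3. The family was lower in 7 of 7 patients (−0.423 ± 0.177, SD, camera adjusted p = 9.91e-12, and adjusted p = 0.252 with an estimated correlation). Cytokine receptor chains rose in 14 and fell in 4 of 33, IL18RAP, a chain of the interleukin 18 receptor, being 6.42-fold and IL12RB2 4.38-fold higher (0.455 ± 0.179, adjusted p = 0.000547; adjusted p = 0.252 with an estimated correlation). SLAM receptors rose in 4 of 6, with CD48 at 5.13-fold (1.56 ± 0.843, adjusted p = 0.00032), and leukocyte immunoglobulin-like receptors in 5 of 8, with LILRA5 at 6.41-fold (1.49 ± 0.784, adjusted p = 0.00023), both at adjusted p = 0.252 with an estimated correlation. The call of CD48 ended without patient 2 (adjusted p = 0.0602), 3 (0.0533) or 6 (0.0697), and that of LILRA5 without patient 6 (0.0562). Chemokine receptors rose in 3 of 12, CCR1 by 7.29-fold (0.562 ± 0.365, adjusted p = 0.0108; adjusted p = 0.303 with an estimated correlation; 0.0536 without patient 3). The cytidine deaminases of the APOBEC3 family rose in 3 of 4, APOBEC3A by 27.7-fold (50.6-fold without patient 7; family 2.15 ± 1.08, adjusted p = 0.00411; adjusted p = 0.297 with an estimated correlation).

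WNT ligands, receptors and inhibitors fell in 10 and rose in 1 of 31, DKK2 by 2.93-fold and WNT4 by 2.71-fold (−0.386 ± 0.245, lower in 7 of 7, adjusted p = 0.00411; adjusted p = 0.303 with an estimated correlation). The call of DKK2 ended without patient 1 (adjusted p = 0.0507), 2 (0.0521) or 6 (0.0537), and that of WNT4 without patient 1 (0.0829), 2 (0.0712), 4 (0.0566) or 6 (0.0719). Claudins, which seal tight junctions, fell in 4 of 14, CLDN1 by 2.41-fold (−0.529 ± 0.315, adjusted p = 0.0306; adjusted p = 0.303 with an estimated correlation). The claudin call ended without patient 1 (adjusted p = 0.0504) and with the block without patient 7 (0.0583). Kynurenine pathway enzymes were not called (0.884 ± 0.491, adjusted p = 0.197), though KMO rose 4.26-fold and KYNU 2.93-fold. TNF receptors (6 of 13 higher, 0.653 ± 0.294, adjusted p = 0.000335), TNF ligands (2 of 8, 0.47 ± 0.346, adjusted p = 0.00686) and the JAK, STAT and SOCS family (4 of 14, 0.468 ± 0.15, adjusted p = 0.00411) were called too, each at adjusted p = 0.252 with an estimated correlation. Interleukins (0.251 ± 0.135, adjusted p = 0.067; adjusted p = 0.303 with an estimated correlation) were called only with the block (0.0473), quantile normalization again (0.0365), arrays centred on their median (0.0475) or without patient 7 (0.0361). Proteasome subunits (0.0772 ± 0.257, adjusted p = 0.197; adjusted p = 0.738 with an estimated correlation) were called only with array weights (mean 0.129, adjusted p = 0.0471), without patient 7 (0.157, adjusted p = 0.0137) or without patient 7 under the block (0.157, adjusted p = 0.0108).

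HOX genes, whose expression in skin depends on the place on the body, fell in 4 of 25 (−0.362 ± 0.444, adjusted p = 0.0108; adjusted p = 0.46 with an estimated correlation; −0.237 and adjusted p = 0.064 without patient 2). The 4 were HOXA2 (1.35-fold), HOXD1 (1.31-fold), HOXD9 (1.25-fold) and HOXB1 (1.22-fold). HOXC6 and HOXC10 were not called (limma adjusted p = 0.238 and 0.118), though HOXC10 was without patient 7 (limma adjusted p = 0.0313). HOXC6 differed by −6.33 to 1.54 between lesional and non-lesional skin and HOXC10 by −3.99 to 1.58, against at most 1.03 and 1.91 between 2 non-lesional samples of a patient, which, if they are repeat arrays of 1 biopsy, hold no difference in site. A difference in body site within some patients is a candidate explanation. The change of these 2 genes followed that of 23 other HOX genes over 7 patients (Pearson r = 0.934, exact permutation p = 0.00536, and Spearman rho = 0.929, exact permutation p = 0.00675). Pearson r was 0.972 without the 2 farthest and 0.983 without patient 7. The 2 genes had the largest decreases of the family. Any cause that moves HOX genes together gives such a correlation, so it does not single out body site. Within patients, the interferon-gamma list was 1.96 ± 0.454 (SE) higher at no difference in the 2 genes, against 2.38 ± 0.413 without this covariate; over unpaired values it was 2.12 ± 0.597 against 2.38 ± 0.528. Part of that increase and the body site cannot be told apart: less 2 SE it stayed above 0 within patients, at 1.05, but below the 1.19 set for excluding the site.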
